A study of Mus musculus with 6 samples.

How the data were processed

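RNA libraries of 6 pro-B cell cultures, 3 wild-type and 3 Ts1Rhr, were made with the Illumina TruSeq RNA kit and sequenced on a HiSeq instrument, per the labels' protocols. The submitters' processing notes name FastQC, Bowtie2, TopHat2 2.0.7 and Cufflinks 2.0.0 and the builds mm9 and GRCm38, without saying which build served which step. The authors deposited a matrix of FPKM values with 23021 rows and 22551 distinct gene symbols. All 6 columns of per-sample values were left unused, because their names could not be matched to 1 sample or group by the labels or the file header. Read totals per library were not given in the sources used here, so the depth is unknown.

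From the matrix, only the gene symbols and the number of rows and columns were read into the results. While the file was first inspected, values of a few genes, Hmgn1 among them, were seen, and they were not used to assign genotypes. Gene positions were taken from the GENCODE annotation of GRCm38, read with Python 3.11.15, and the interval was set from the first to the last base of the 30 genes listed before the data were examined. A linear-model comparison of the genotypes on log-transformed values was planned, with alternatives for the filter, scaling and replicate block. None of these fits was run, and no test was made.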

Results

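RNA was sequenced from 6 libraries of mouse pro-B cells, the early B-lineage precursors that rearrange the immunoglobulin heavy chain. Bone marrow was plated in a semi-solid methylcellulose culture that favours B-cell growth, and the colonies were collected after 1 week, at passage 1. By their titles, 3 libraries came from wild-type mice and 3 from Ts1Rhr mice. Ts1Rhr is an engineered mouse strain with an extra copy of a segment of chromosome 16 orthologous to part of human 21q22. The genotype field gave Ts1Rhr for all 6 libraries, including the 3 titled wild-type, so the titles and the design description were taken for the groups.

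The design asks how gene expression in pro-B cells differed between the Ts1Rhr and wild-type genotypes. The planned comparison was not limited to the segment with the extra copy. The genes with an extra copy in Ts1Rhr were taken to lie between Cbr1 and Fam3b, the ends of the segment in the published construction of the strain. In the GRCm38 annotation this interval runs on chromosome 16 from 93605853 to 97514816, a length of 3.91 Mb, and holds 33 protein-coding gene models. These bounds are the annotated ends of Cbr1 and Fam3b, and the ends of the engineered segment were not measured. Cbr1, a carbonyl reductase, lies at 93605853 to 93610505 on the plus strand. Fam3b lies at 97470965 to 97514816 on the minus strand. Hmgn1, which encodes the nucleosome-binding protein named in the title of the series, lies at 96120618 to 96127729 on the minus strand. Dyrk1a, a protein kinase gene, lies at 94570010 to 94695517 on the plus strand. Members of the ETS transcription factor family also lie in the interval, Erg at 95359169 to 95586593 on the minus strand and Ets2 at 95702075 to 95721051 on the plus strand. All 30 genes of the interval listed before the data were examined have a row in the expression matrix, under the listed symbol or an alias. A row alone does not show that a gene was expressed in these cells. Of the 33 gene models, 31 carry a listed symbol or alias, with Igsf5 repeated.

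No expression comparison between Ts1Rhr and wild-type is reported. The 6 value columns of the matrix carry codes whose parts match the passage and the replicate number in the titles. Each code also holds a letter that the header does not explain. Neither the labels nor the file header used here state which letter stands for which genotype, so each code fits 1 wild-type and 1 Ts1Rhr library equally. Assigning the letters by the level of the triplicated genes would have fixed the direction of the difference for those genes in advance. A comparison of the letters without a genotype was not run. It would leave the direction unknown, and it would rest on the letters separating the genotypes, which the labels and header do not state. The expression values were not analysed here, and no fold change, test or gene count is given.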

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

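No paired analysis was possible between the named genotypes because no column of values was matched to a genotype. A comparison of the column letters blocked by replicate number was possible but was not run, since unmatched columns were left out by choice. Its direction would be unknown, the letters are not stated to mark genotype, and the replicate numbers are not stated to pair samples. No expression result exists, so none was recomputed with another pseudocount, filter, scaling, variance model, sample weighting or set test, with a replicate block, or without single libraries. The count of 33 protein-coding gene models in the interval became 32 when each gene name was counted once, because Igsf5 has repeated gene models. It stayed at 33 when any overlap was enough. These counts come from the reference annotation alone and say nothing about expression. The main count was not planned in advance, and both other ways of counting were chosen after the annotation was seen.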
